A study of Mus musculus with 104 samples.

How the data were processed

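Bulk RNA-seq libraries of mouse cells were read from 18 deposited tables of counts per gene symbol (104 libraries, 24984 genes each). The counts were made by the authors with Trimmomatic, HISAT2 and featureCounts per the submitters' processing notes, which give no versions and name the builds mm10 and hg38; the annotation and read pairing are not stated. The labels name the VAHTS Universal V8 kit. Low counts were even in 59.3% to 87.7% of genes (median 67.4%), as when both mates of a pair are counted, so p-values were also computed with halved counts. In every deposited file, 26 genes whose names had turned into dates were left out, leaving 24958. No column of the tables went unused.

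Libraries were grouped by their labels alone, into 24 groups. The mPSC group held 3 libraries in S/L medium, 1 of them titled as passage 0 of the 2MYCP series, and established mTBLCs were passages 6, 8, 14 and 19. The labels do not expand the names 2MYCP, 2MYC, 2MYP, SFH, NTF, TNKM, TELC and PreLC. The deposited name of the 2MYP counts reads without-CHIR, which names the component abbreviated C. The ZHBTc4 libraries other than passages 1 to 4 with doxycycline were reported as levels without a test.

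Counts were fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F test), and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to rise, fall, change or pass. The standard error is the log2 fold change over the square root of F. Groups sharing a fit shared their spread: mPSCs, mTBLCs, gelatin, 2MYP, the Ctnnb1 knock-out and ICG001 were 1 fit, the blastomere-derived lines with mPSCs and mTBLCs a second, and TELC, PreLC, EB-TSC, blastoids and the blastocyst another. A group with 1 library was assumed to vary like the others of its fit. 2MYCP was set against 2MYC with passage as a block, and embryoid bodies with day as a block. The courses were fitted as natural splines of hours with 3 degrees of freedom (2 for NTF), testing 92 h against 0 h (96 h for NTF), and the SFH and S/L courses by the interaction. The passage trend used log2 of passage plus 1. Comparisons sharing control libraries are not independent.

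For 20 gene lists fixed beforehand (383 members, 382 present), the 2-cell, naive pluripotency, trophectoderm, placental, primitive endoderm, visceral endoderm, formative, mesoderm, cardiac, blood, neural, Wnt target, p53 target, spliceosome, stress, proliferation, DNA methylation, germline, imprinted and fibroblast lists, members past the test were counted, over all genes and adjusted over the list alone. Each list was tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation. Of 378 list tests 139 passed with the preset and 15 with the estimated correlation, and a selection of these is described.

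Genes were named by a rule set before the data were examined: Pou5f1, Sox2, Nanog, Zfp42, Zscan4c, Zfp352, Cdx2, Gata3, Krt8, Gata6, Sox17 and Fgf5 whatever their result, with Ctnnb1 and Axin2 in the knock-out, ICG001 and 2MYP comparisons. To these the rule adds up to 4 members per direction of a described list with the largest changes that passed, and the 5 largest changes per direction with a mean of at least 5 CPM, leaving out gene models. The text does not name all that the rule selects: of 1325 genes selected over 19 comparisons it names at least 329. Of 228 values of the 12 fixed genes it gives at least 87, and those left out, at most 141, did not pass the test. Gene values of single libraries and of embryoid body libraries outside this rule (Col1a1) were chosen after values were seen. A gene with 0 counts in a group is given a least fold, with a floor of 3 counts over the group, which covers counting error only.

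The groups, tests, lists, naming rule and first alternatives were chosen before the data were examined. These alternatives were DESeq2 size factors, no filter or a stricter one, the Wald test of DESeq2 1.42.0, leaving out each library, other controls, other splines, blocks and matched subsets. Added after the data were seen were halved counts, removal of each library's gene length trend (lengths from mouse annotation release 21, for 98.2% of genes), fits without the passage 0 library or TELC passages 1 and 2, embryoid bodies without days 3 and 8, ZHBTc4 passages 2 and 4 alone, and the NTF course without 4 h and 24 h.

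Pairing was checked by correlating the deviations from group means of libraries with the same number: 0.01 to 0.12 for 2MYCP and 2MYC passages, 0.06 to 0.26 for TELC and PreLC, 0.32 in both pairs of blastomere-derived lines, 0.00 to 0.06 for ZHBTc4, and 0.12, 0.33, 0.52 and 0.59 for embryoid bodies at days 3, 8, 10 and 12. The analysis was tested on simulated data with 200 genes changed 2-fold or 4-fold. Of 4-fold changes 73% were found for mTBLCs against mPSCs, 82% in the S/L and 64% in the SFH course, 38% on gelatin, 29% for 2MYP, 8% for the knock-out, 17% for ICG001, 14% for embryoid bodies, and 0% for the passage trend, TELC and blastoids, with at most 6 false calls and 0 in the wrong direction. Of 2-fold changes 4% were found for mTBLCs against mPSCs, 54% for 2MYCP against 2MYC, and 41% and 44% in the S/L and SFH courses. On gelatin, for 2MYP, the knock-out and ICG001, 0% of these were found. The simulated counts held no gene length trend, so the false calls given do not cover it. Tables were handled with Python 3.11.15 and pandas 2.3.3.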

Results

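Bulk RNA-seq measured the mRNA of 104 mouse libraries in 24 groups, read here as counts of 24958 genes. The cells were TC1-GFP pluripotent stem cells (mPSCs) in S/L medium (n = 3), cells in a medium named 2MYCP, called totipotent blastomere-like cells or mTBLCs (n = 7, passages 1 to 19), and variants of that culture: on gelatin (n = 2), without the component abbreviated P (2MYC, n = 6) or C (2MYP, n = 2), with Ctnnb1 knocked out (n = 1), and with ICG001, an inhibitor of the partnership of beta-catenin with CBP (n = 1). Libraries titled ZHBTc4, a line in which doxycycline silences Pou5f1, came from S/L medium without (n = 1) and with doxycycline (n = 1), 2MYCP medium without (n = 1) and with doxycycline (n = 5), and 2MYC medium with doxycycline (n = 2). The titles name doxycycline in the S/L and 2MYCP libraries counted as with it, but not in the 2MYC libraries. mTBLCs were followed for up to 92 h in S/L (n = 20), 96 h in SFH (n = 23) and 96 h in NTF medium (n = 7). The S/L and SFH titles write the time with a d, read here as hours, and the NTF titles with an h. Lines derived from blastomeres were grown at 2 doses labelled 4nM (n = 2) and 2-5nM (n = 2). The rest were TELC (n = 3), PreLC (n = 3) and EB-TSC (n = 1) cells, blastoids (n = 2), an E3.5 blastocyst sample (n = 1), and embryoid bodies from TC1 cells (n = 4) and from mTBLCs (n = 4).

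Total counts ranged from 1.04 M in a ZHBTc4 library in 2MYC medium with doxycycline to 57 M in an S/L course library, with a median of 22.8 M (M, mega). Libraries set against each other often differed in depth: mPSCs had 7.28 to 26.7 M, 2MYCP 20.2 to 42.3, 2MYC 6.26 to 7.98, 2MYP 10.5 to 11.1, and the S/L, SFH and NTF courses 35.6 to 57, 12.6 to 28.3 and 5.10 to 36.4. TELC had 8.73 to 19.4 M and PreLC 33.2 to 40.7. Expression is given in CPM, counts scaled to library size and by TMM, as mean ± SD, and fold changes as log2 ± SE. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

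The first comparison set established mTBLCs (passages 6, 8, 14 and 19, n = 4) against mPSCs in S/L medium (n = 3). Genes of the 2-cell embryo were much higher in mTBLCs. Zscan4c, a marker of 2-cell-like cells, stood at 71.4 ± 13.9 against 3.79 ± 3.57 CPM (log2 fold change 4.25 ± 0.81, adjusted p = 0.00503), and Zfp352 rose by a log2 fold change of 5.24, Usp17ld by 6.23 and Pramel6 by 6.08 (highest adjusted p = 0.00193). For the 33 2-cell genes tested, 30 rose, 0 fell and 3 did not pass (32 and 1 adjusted over the list alone, camera adjusted p = 1.15e-45, adjusted p = 0.0788 with an estimated correlation). Reads of the Zscan4, Usp17l, Tdpoz and Pramel paralogs are hard to tell apart, so the split within each family is uncertain.

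Pou5f1, a core pluripotency factor, fell to 809 ± 124 against 1889 ± 462 CPM (log2 fold change -1.22 ± 0.22, adjusted p = 0.00417), and with it Dppa5a (-2.16), Lin28a (-1.52) and Utf1 (-1.41). Nanog, at 544 ± 139.8 against 363 ± 112 CPM (adjusted p = 0.159), did not pass the test. For the 20 naive pluripotency genes tested, 0 rose, 7 fell and 13 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.0366, adjusted p = 0.577 with an estimated correlation). Gata6 (2.79), Hnf4a (2.19) and Sox7 (2.03), endoderm transcription factors, rose. For the 20 primitive endoderm genes tested, 8 rose, 0 fell and 12 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.577 with an estimated correlation). The p53 target genes Btg2 (176 ± 23.5 against 39.4 ± 8.13 CPM, log2 fold change 2.16 ± 0.23, adjusted p = 3.44e-04), Mdm2 (1.46) and Trp53inp1 (1.69) rose, as did the Wnt targets Axin2 (38.9 ± 7.49 against 10.1 ± 4.06 CPM, log2 fold change 1.96 ± 0.32, adjusted p = 0.0024), Notum (1.99) and Apcdd1 (1.77). For the 17 Wnt targets tested, 5 rose, 0 fell and 12 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.278 with an estimated correlation).

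The proliferation genes Mcm6 (-1.01) and Cdk1 (-0.85) fell. For the 17 proliferation genes tested, 0 rose, 5 fell and 12 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.577 with an estimated correlation). The netrin receptor gene Dcc rose the most among genes of at least 5 CPM on average (log2 fold change 7.09 ± 0.68, adjusted p = 2.43e-04), and the interferon-response genes Irf7 (-4.76) and Usp18 (-4.85) fell the most next to Ccl5 and Sprr2h. In edgeR, 1671 of 17525 genes rose and 1731 fell. Leaving out 1 mTBLC library gave 2218 genes without P6, 2024 without P8, 1668 without P14 and 1592 without P19, and the 3 course libraries at 0 h in place of these mTBLCs gave 1353. The mPSC library titled as passage 0 had a log2 expression slope of -1.87 per log10 of gene length, against 0.17 and 0.28 in the other mPSC libraries, with 15% of counts in ribosomal protein genes against 6.50% and 6.31%.

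**Figure D1:**
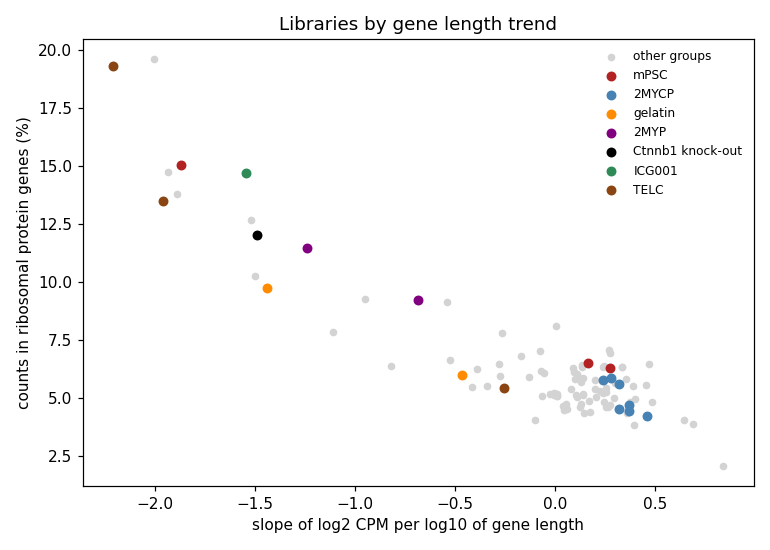
Share of counts in ribosomal protein genes against the slope of log2 CPM per log10 of gene length, 1 point per library (n = 104), coloured by group. The knock-out, ICG001, 2MYP, gelatin and passage 0 libraries lie to the left of the 2MYCP libraries, which have slopes of 0.24 to 0.46.

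Along passages 0 to 19 (8 libraries, 1 per passage), changes per doubling of passage plus 1 were fitted. The passage 0 library is an mPSC library labelled as grown in S/L medium. Changes that rest on it cannot be told from the change of medium or from its gene length trend, given above. Some endoderm genes rose along this series: Foxq1 by 1.01, Lama1 by 0.74, Sox7 by 0.76 and Gata4 by 0.64 (highest adjusted p = 0.0387). Of 20 tested primitive endoderm genes, 6 rose, 0 fell and 14 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 2.38e-08, adjusted p = 0.555 with an estimated correlation). The X-linked gene Xlr3c rose by 2.05 and the serpin Serpina3n by 1.64, while Pou5f1 fell by 0.35 (adjusted p = 0.0333), from 2649 CPM at passage 0. Zscan4c rose by 0.55 (adjusted p = 0.048). Of 32 tested 2-cell genes, 4 rose, 1 fell and 27 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 5.90e-11, adjusted p = 0.555 with an estimated correlation).

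The spliceosome genes Snrpd2 (-0.65), Snrpe (-0.49), Snrpa1 (-0.33) and Phf5a (-0.32) fell. For the 29 spliceosome genes tested, 0 rose, 7 fell and 22 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 0.00321, adjusted p = 0.555 with an estimated correlation). The imprinted gene Peg3 (0.70) rose and the p53 target Bax (-0.26) fell. In edgeR 584 of 16330 genes rose and 1240 fell, and with DESeq2 3642 changed. The trend rested on single libraries: 3046 genes without passage 1, 746 without P4, 14 without P6, 11 without P8, 0 without P14 (4121 at an unadjusted p under 0.05) and 3 without P19. Without passage 0, whose length slope is given above, 771 rose and 367 fell, 475 of them shared with the full set, and with passage as a plain number 0 genes passed in edgeR (2600 at an unadjusted p under 0.05).

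Cells in 2MYCP and 2MYC medium, which differ by the component abbreviated P, were compared at passages 1, 2, 4 and 6 (4 against 4, passage as a block). The libraries of the 2 media were deposited in separate sets, with 20.2 to 42.3 M and 6.26 to 7.98 M counts. An effect of P therefore cannot be told from a difference between these sets. Wnt targets higher with P included Axin2, a feedback inhibitor of Wnt signalling, at 92.8 ± 45.0 against 6.51 ± 5.67 CPM (log2 fold change 3.89 ± 0.65, adjusted p = 0.0107), with Wnt3a (3.91), Sp5 (3.78) and Dkk1 (3.46). Of 17 tested Wnt targets, 7 rose, 0 fell and 10 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 1.98e-07, adjusted p = 0.349 with an estimated correlation). The 2-cell genes rose too, with Zscan4c at 53.2 ± 9.85 against 5.33 ± 3.32 CPM (log2 fold change 3.41 ± 0.39, adjusted p = 0.004), Zfp352 (3.69), Zscan4b (4.22) and Usp17lc (4.08). For the 31 2-cell genes tested, 24 rose, 0 fell and 7 did not pass (29 and 0 adjusted over the list alone, camera adjusted p = 1.56e-36, adjusted p = 0.349 with an estimated correlation). Cdx2, a trophectoderm factor, was low in both but higher with P (4.36 ± 4.45 against 0.0655 ± 0.131 CPM, log2 fold change 5.66 ± 0.97, adjusted p = 0.0119), and Eomes rose (2.49).

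Among p53 targets Cdkn1a rose from 155 ± 36.5 to 458 ± 109 CPM (log2 fold change 1.56 ± 0.17, adjusted p = 0.004), with Perp (1.18) and Pmaip1 (1.10). For the 20 p53 targets tested, 11 rose, 0 fell and 9 did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 4.88e-09, adjusted p = 0.484 with an estimated correlation). Endoderm genes Gata6 (2.62), Sox17 (2.54) and Cubn (4.13) rose. For the 20 primitive endoderm genes tested, 5 rose, 0 fell and 15 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 6.44e-04, adjusted p = 0.532 with an estimated correlation). The mesoderm genes Bmp4 (1.87) and Kdr (2.46) rose, with Tbx20 (-1.79) lower. For the 17 mesoderm genes tested, 4 rose, 1 fell and 12 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.00863, adjusted p = 0.349 with an estimated correlation). The splicing factor gene Sf3b3 rose from 382 ± 82.0 to 1030.0 ± 94.6 CPM (log2 fold change 1.46 ± 0.14, adjusted p = 0.00287).

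Lower with P were the naive genes Tcl1 (-1.40), Nr0b1 (-1.30), Fgf4 (-0.95) and Prdm14 (-0.84). Of 20 tested naive pluripotency genes, 0 rose, 4 fell and 16 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 6.44e-04, adjusted p = 0.53 with an estimated correlation). Otx2, a factor of the epiblast, was at 14.9 ± 22.5 against 96.3 ± 9.86 CPM (log2 fold change -3.95 ± 0.78, adjusted p = 0.019). Serine synthesis genes Phgdh (-1.09) and Psat1 (-1.08) fell. For the 15 stress genes tested, 0 rose, 5 fell and 10 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 6.44e-04, adjusted p = 0.53 with an estimated correlation). In edgeR 974 of 15291 genes rose and 975 fell, with 3090 in DESeq2. Leaving out one passage gave 407 genes without passage 1, 215 without passage 2 and 792 without passage 4.

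mTBLCs on gelatin (passages 7 and 8, n = 2) were compared with established mTBLCs (n = 4), to see what the surface changes. Fibroblast genes were nearly gone on gelatin. Collagen gene Col3a1 had 0 counts in both gelatin libraries against 55.8 ± 16.7 CPM (at least 1282-fold lower, with a floor of 3 counts over the group), and Col6a3 stood at 0.0511 ± 0.0722 against 124 ± 41.8 CPM, Prrx1 at 0.0255 ± 0.0361 against 182 ± 52.0 CPM and Lox at 0.0255 ± 0.0361 against 253 ± 85.7 CPM (highest adjusted p = 1.54e-04). For the 15 fibroblast genes tested, 0 rose, 13 fell and 2 did not pass (0 and 14 adjusted over the list alone, camera adjusted p = 6.28e-21, adjusted p = 0.156 with an estimated correlation). The labels do not say whether the other 2MYCP cultures grew on feeder cells.

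The keratin genes Krt8 (157 ± 9.91 against 41.7 ± 13.9 CPM, log2 fold change 1.92 ± 0.39, adjusted p = 0.00843) and Krt18 (1.99) and the tight junction gene Cldn4 (2.65), of the trophectoderm list, rose on gelatin. For the 25 trophectoderm genes tested, 5 rose, 0 fell and 20 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.54 with an estimated correlation). Pou5f1 (1.09), Dppa5a (1.95), Klf2 (0.92) and Dppa4 (0.91) rose. For the 20 naive pluripotency genes tested, 4 rose, 0 fell and 16 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.54 with an estimated correlation). Pramel6 (2.84), Pramel7 (2.23) and Dppa3 (2.25) rose among 2-cell genes, while Zscan4c was 97.1 ± 47.7 against 71.4 ± 13.9 CPM (adjusted p = 0.71). Of 33 tested 2-cell genes, 3 rose, 0 fell and 30 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.552 with an estimated correlation). The Wnt targets Cdx1 (3.83) and Sp5 (3.24) were among the largest rises. Otx2 (-3.60), Cdh2 (-2.78) and Fgf15 (-2.86) fell. For the 15 formative genes tested, 1 rose, 5 fell and 9 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.00328, adjusted p = 0.321 with an estimated correlation).

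The imprinted genes Igf2 (-4.33) and Zim1 (-3.26) fell, as did Cubn (-5.47). For the 21 imprinted genes tested, 0 rose, 3 fell and 18 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.321 with an estimated correlation). Small spliceosome genes such as Snrpb (1.26) and Phf5a (1.43) rose. Of 29 tested spliceosome genes, 10 rose, 0 fell and 19 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 1.32e-05, adjusted p = 0.357 with an estimated correlation). The gelatin libraries had length slopes of -1.44 and -0.47 against 0.32 to 0.46 in the other mTBLCs. In edgeR 1354 of 17525 genes rose and 1509 fell, and DESeq2 gave 4429. The rises depended on single libraries: 84 rose and 382 fell without gelatin P7, and 35 and 383 with P6 and P8 as controls (466 and 418 in all). In neither fit did Krt18, Pou5f1, Dppa5a, Klf2, Dppa4, Dppa3, Cdx1, Snrpb, Phf5a, Cdh2, Igf2, Zim1 or Cubn pass, while Col3a1, Col6a3, Prrx1, Lox, Cldn4, Pramel7 and Otx2 passed in both. Pramel6 and Sp5 passed in the first alone and Krt8 in the second alone. Counts up and down were 454 and 626 without gelatin P8, 532 and 1173 without mTBLC P6, 272 and 990 without P8, 362 and 912 without P14, 202 and 792 without P19, and 3375 and 3143 in a fit without the passage 0 library.

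Without the component abbreviated C (2MYP medium, passages 7 and 8, n = 2, against n = 4), Axin2 was 11.1 ± 1.34 against 38.9 ± 7.49 CPM (log2 fold change -1.82 ± 0.37, adjusted p = 0.0238), while Ctnnb1, which encodes beta-catenin, was 807 ± 125 against 819 ± 34.5 CPM (adjusted p = 0.982). For the 17 Wnt targets tested, 0 rose, 1 fell and 16 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.127, adjusted p = 0.42 with an estimated correlation). Pou5f1 rose to 2080.0 ± 228 against 809 ± 124 CPM (log2 fold change 1.36 ± 0.25, adjusted p = 0.0174), with Dppa5a (2.15), Tcl1 (1.87) and Dppa4 (1.12). Of 20 tested naive pluripotency genes, 4 rose, 0 fell and 16 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 2.67e-04, adjusted p = 0.42 with an estimated correlation). Otx2 rose (1.60), and Cdh2 fell (-2.50). Pramel6 (2.15) and AF067061 (2.18) rose among the 2-cell genes, and Zscan4c was 175 ± 54.1 against 71.4 ± 13.9 CPM (adjusted p = 0.259). For the 33 2-cell genes tested, 4 rose, 0 fell and 29 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 1.80e-05, adjusted p = 0.42 with an estimated correlation).

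The proliferation genes Mcm7 (1.17), Aurka (1.07) and Mcm6 (0.85) rose. Of 17 tested proliferation genes, 4 rose, 0 fell and 13 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 1.24e-04, adjusted p = 0.42 with an estimated correlation). Among imprinted genes the growth factor Igf2 (-3.82) and Plagl1 (-1.92) fell. Of 21 tested imprinted genes, 0 rose, 4 fell and 17 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.42 with an estimated correlation). The spliceosome genes Phf5a (1.41) and Snrpb (1.05) rose. For the 29 spliceosome genes tested, 3 rose, 0 fell and 26 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 1.57e-04, adjusted p = 0.42 with an estimated correlation). Col6a3 (-2.11) and the p53 target Perp (-1.25) fell. The ribosomal protein paralog Rpl22l1 was among the largest rises (log2 fold change 2.78 ± 0.24, adjusted p = 9.50e-04). The length slopes of these libraries were -1.24 and -0.69, with 11.5% and 9.24% ribosomal protein counts against 4.24% to 4.70% in the controls.

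In edgeR 526 of 17525 genes rose and 580 fell, with 3006 in DESeq2. These calls rested on single libraries: 1 gene passed without 2MYP P7, 1 without 2MYP P8, 446 without mTBLC P6, 63 without P8, 19 without P14 and 1 without P19. With P6 and P8 as controls 0 passed in edgeR (2317 at an unadjusted p under 0.05), and 5029 passed in a fit without the passage 0 library.

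In the Ctnnb1 knock-out library (passage 7, n = 1, against n = 4) Ctnnb1 itself was at 178 against 819 ± 34.5 CPM, a log2 fold change of -2.20 (adjusted p = 0.123) that did not pass the test. The test borrowed its spread from the replicated groups of the same fit. Axin2 was at 18.8 against 38.9 ± 7.49 CPM (adjusted p = 0.216), and Nanog at 207 against 544 ± 139.8 CPM (adjusted p = 0.134). Of 17 tested Wnt targets, 0 rose, 0 fell and 17 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.16, adjusted p = 0.76 with an estimated correlation). Mir703 was the single gene called (102 against 8.62 ± 1.41 CPM, log2 fold change 3.56 ± 0.43, adjusted p = 0.0379). By camera placental genes (0 rose, 0 fell and 7 did not pass of 7, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.486 with an estimated correlation) and spliceosome genes (0 rose, 0 fell and 29 did not pass of 29, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.773 with an estimated correlation) ranked higher, and proliferation genes (0 rose, 0 fell and 17 did not pass of 17, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.794 with an estimated correlation) and imprinted genes (0 rose, 0 fell and 21 did not pass of 21, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.607 with an estimated correlation) lower.

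In edgeR 1 gene passed and 3839 had an unadjusted p under 0.05, while DESeq2 called 673 higher and 893 lower. The edgeR count was 63 with no filter, 0 with a stricter filter, 8 with counts halved, 100 with the length trend removed, 0 without mTBLC P6, P8 or P19, 0 with P6 and P8 as controls, and 4277 in a fit without the passage 0 library. The knock-out library had a length slope of -1.49 and 12.0% ribosomal protein counts, against 0.32 to 0.46 and 4.24% to 4.70% in its controls.

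In the library with ICG001 (passage 7, n = 1, against n = 4), Axin2 was 27.7 against 38.9 ± 7.49 CPM (adjusted p = 0.467) and Ctnnb1 468 against 819 ± 34.5 CPM (adjusted p = 0.37). Among Wnt targets Ccnd1 (-2.15) and T (-3.72) fell and Cdx1 rose (2.91). For the 17 Wnt targets tested, 1 rose, 2 fell and 14 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.451, adjusted p = 0.616 with an estimated correlation). The stress genes Ddit3 (205 against 29.4 ± 9.09 CPM, log2 fold change 2.81 ± 0.74, adjusted p = 0.0297), Nupr1 (2.71), Asns (2.23) and Trib3 (2.22) rose. Of 15 tested stress genes, 7 rose, 0 fell and 8 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 5.50e-05, adjusted p = 0.471 with an estimated correlation). Of the endoderm list, the collagen genes Col4a1 (52.3 against 745 ± 351 CPM, log2 fold change -3.83) and Col4a2 (-3.72) and the endocytic receptor Cubn (-8.55) fell. Of 20 tested primitive endoderm genes, 0 rose, 5 fell and 15 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 5.50e-05, adjusted p = 0.528 with an estimated correlation). The formative genes Fgf15 (-5.20), Otx2 (-2.95) and Pou3f1 (-2.74) fell. Of 15 tested formative genes, 0 rose, 5 fell and 10 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 5.50e-05, adjusted p = 0.302 with an estimated correlation).

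Pramel6 (446 against 10.5 ± 3.56 CPM, log2 fold change 5.41 ± 0.56, adjusted p = 7.95e-04), Dppa3 (4.79) and Pramel7 (3.98) rose, and Zscan4c was 47.7 against 71.4 ± 13.9 CPM (adjusted p = 0.714). Of 33 tested 2-cell genes, 5 rose, 1 fell and 27 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.616 with an estimated correlation). Pou5f1 rose (1.10, adjusted p = 0.0366), a call lost without any 1 of the mTBLC libraries or with the length trend removed. Germline genes Dazl (2.41) and Asz1 (3.17) rose and Ddx4 fell (-2.85). For the 20 germline genes tested, 7 rose, 1 fell and 12 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.528 with an estimated correlation). Fibroblast genes Col3a1 (-7.29) and Col6a3 (-4.13), the imprinted gene Peg3 (-6.77) and the proliferation marker Mki67 (-2.12) fell. The T cell gene Cd3d (50.1 against 0.445 ± 0.524 CPM) was among the largest rises (log2 fold change 6.81 ± 0.95, adjusted p = 0.00429). This library had a length slope of -1.54 and 14.7% ribosomal protein counts. In edgeR 1597 of 17525 genes rose and 810 fell (66.3% up), while DESeq2 gave 2054 and 2134 (49.0% up). The count fell with fewer mTBLC libraries, as given below.

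Lines derived from blastomeres of ICR embryos (2iLP medium, passages 4 and 5, n = 4) were compared with mPSCs (n = 3) and with established mTBLCs (n = 4), which are TC1-GFP cells. The strain, the medium and the origin differ together. Against mPSCs, Zfp352 rose (3.29 ± 2.00 against 0.426 ± 0.563 CPM, log2 fold change 3.19 ± 0.82, adjusted p = 0.0142), with Gm20767 (6.46), Pramel7 (5.60) and Tcstv1 (4.56). Zscan4c, at 5.44 against 4.0 CPM (log2 fold change 0.42, adjusted p = 0.701), did not pass the test. For the 32 2-cell genes tested, 25 rose, 0 fell and 7 did not pass (28 and 0 adjusted over the list alone, camera adjusted p = 8.96e-19, adjusted p = 0.395 with an estimated correlation). Nanog rose to 919 ± 42.3 against 373 ± 105 CPM (log2 fold change 1.30 ± 0.27, adjusted p = 0.00499), Pou5f1 fell (-0.74, adjusted p = 0.0438), Lin28a (-2.63) and Utf1 (-2.20) fell, and Krt8 fell to 3.62 ± 1.24 against 35.3 ± 17.6 CPM (log2 fold change -3.29 ± 0.41, adjusted p = 3.18e-04).

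Axin2 (2.34), Apcdd1 (3.12) and the stem cell receptor Lgr5 (3.56) rose and Bmp4 fell (-3.37). Of 18 tested Wnt targets, 9 rose, 1 fell and 8 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 0.00868, adjusted p = 0.395 with an estimated correlation). Cubn (-6.74), Sox17 (-2.69, a call lost in 4 of 7 fits without 1 library) and Sox7 (-5.46) fell. For the 20 primitive endoderm genes tested, 0 rose, 7 fell and 13 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.651 with an estimated correlation). Col3a1 stood at 953 ± 242 against 23.9 ± 8.01 CPM (log2 fold change 5.30 ± 0.39, adjusted p = 3.98e-05) and Col1a1 rose (2.52), while Mgp fell (-5.71). Of 15 tested fibroblast genes, 8 rose, 4 fell and 3 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.00285, adjusted p = 0.643 with an estimated correlation). The meiosis genes Dazl (4.00) and Hormad1 (3.29) rose. The nuclear receptor gene Nr1h5 was at 219.6 ± 28.5 CPM and had 0 counts in every mPSC library (at least 3943-fold higher). In edgeR 2081 of 16768 genes rose and 2409 fell. The count was 2890 without 2-5nM P5 and 2781 without 2-5nM P4.

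Against mTBLCs the same lines had lower 2-cell and endoderm genes. Zscan4c was 5.44 ± 1.65 against 73.0 ± 14.5 CPM (log2 fold change -3.78 ± 0.69, adjusted p = 0.0028), Zfp352 fell (-1.98), and Dppa3, a maternal factor, rose (43.6 ± 21.5 against 1.04 ± 0.192 CPM, log2 fold change 5.39 ± 0.72, adjusted p = 5.28e-04). Of 32 tested 2-cell genes, 1 rose, 19 fell and 12 did not pass (3 and 22 adjusted over the list alone, camera adjusted p = 7.47e-06, adjusted p = 0.611 with an estimated correlation). Gata6 (2.75 ± 0.589 against 48.9 ± 36.5 CPM, log2 fold change -4.14 ± 0.61, adjusted p = 8.84e-04), Sox17 (-4.44), Sox7 (-7.49) and Cubn (-8.50) fell. Of 20 tested primitive endoderm genes, 0 rose, 17 fell and 3 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 6.84e-09, adjusted p = 0.611 with an estimated correlation). Krt8 (-3.56) and Fgf5 (0.217 ± 0.181 against 1.39 ± 0.369 CPM, adjusted p = 0.0219, a call lost in 5 of 8 fits without 1 library) fell, and Nanog rose (0.72, adjusted p = 0.0433). Cdk1 (1.04), Mcm6 (0.98) and Plk1 (0.98) rose. For the 17 proliferation genes tested, 9 rose, 0 fell and 8 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 0.00215, adjusted p = 0.611 with an estimated correlation). Col3a1 (4.04) and Postn (3.31) rose while Mgp fell (-7.92). In edgeR 2172 of 16768 genes rose and 2497 fell. The count was 2612 without 4nM P4, 2888 without 2-5nM P5, 2540 without 2-5nM P4, 2929 without mTBLC P19, and 7859 in a fit without the passage 0 library.

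Between the 4nM and 2-5nM lines (2 against 2), Zscan4c was 6.69 ± 0.583 against 4.19 ± 1.23 CPM and Zfp352 4.99 ± 0.606 against 1.59 ± 0.319 CPM, and no gene passed. In edgeR 0 of 16768 genes passed, 132 had an unadjusted p under 0.05, and DESeq2 called 0. Higher in 4nM by camera were 2-cell genes (0 rose, 0 fell and 32 did not pass of 32, 0 and 0 adjusted over the list alone, camera adjusted p = 7.78e-30, adjusted p = 0.244 with an estimated correlation), with a median log2 difference of 1.21.

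ZHBTc4 cells with doxycycline in 2MYCP medium (passages 1 to 4, n = 4) were set against TC1-GFP mTBLCs at passages 1, 2 and 4 (n = 3), to see what follows when Pou5f1 is silenced. The cell line field of these labels reads TC1-GFP, and the titles name ZHBTc4. Line and doxycycline differ together. Pou5f1 was 5.80 ± 7.83 against 1074 ± 83.0 CPM (log2 fold change -7.56 ± 1.30, adjusted p = 0.00679). Sox2 (5.93 ± 4.00 against 457 ± 205 CPM, log2 fold change -6.28 ± 0.59, adjusted p = 9.05e-04), Nanog (-5.66), Zfp42 (-5.02) and Fgf4 (-8.27) fell with it. For the 20 naive pluripotency genes tested, 0 rose, 16 fell and 4 did not pass (0 and 16 adjusted over the list alone, camera adjusted p = 2.22e-19, adjusted p = 0.169 with an estimated correlation). Of the trophectoderm list, the keratin genes Krt8 (2269 ± 844 against 36.5 ± 16.3 CPM, log2 fold change 5.96 ± 0.49, adjusted p = 6.79e-04) and Krt18 (7.59), Hand1 (8.11), Gata3 (3.76) and Plac1 (7.38) rose, while Eomes fell (-2.95) and Cdx2 was 11.6 ± 18.4 against 5.68 ± 4.48 CPM (adjusted p = 0.565, with a log2 fold change of 1.03, and -1.16 without ZHBTc4 passage 1). Of 25 tested trophectoderm genes, 16 rose, 1 fell and 8 did not pass (17 and 3 adjusted over the list alone, camera adjusted p = 1.17e-12, adjusted p = 0.169 with an estimated correlation).

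The syncytiotrophoblast genes Gcm1 (5.28) and Syna (5.41) rose. For the 4 placental genes tested, 4 rose, 0 fell and 0 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.00626, adjusted p = 0.172 with an estimated correlation). The placental list has 20 members, and the others were too low in these libraries to pass the filter. A gene high in 1 arm alone can pass it, so a rise of all those tested was likely beforehand. The imprinted genes Igf2 (5.24), Peg10 (5.43) and Cdkn1c (5.31) rose too. Atf3 (4.27) and Ddit3 (3.77) rose and Asns fell (-1.49). For the 15 stress genes tested, 7 rose, 1 fell and 7 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.00444, adjusted p = 0.484 with an estimated correlation). Bbc3 (2.22) and Phlda3 (2.21), p53 targets, rose. Mki67 (-3.46) and Top2a (-2.83) fell. Of 17 tested proliferation genes, 0 rose, 9 fell and 8 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 1.07e-06, adjusted p = 0.587 with an estimated correlation). Zfp57 (-4.59), which guards imprints, and Tet1 (-4.29) fell. For the 10 DNA methylation genes tested, 0 rose, 4 fell and 6 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 9.45e-04, adjusted p = 0.408 with an estimated correlation). Zscan4c was 29.8 ± 41.1 against 51.6 ± 11.2 CPM (adjusted p = 0.733), Zfp352 5.52 ± 6.59 against 7.54 ± 2.80 CPM (adjusted p = 0.827) and Sox17 30.1 ± 34.2 against 2.11 ± 1.29 CPM (adjusted p = 0.122), means that hide a split by passage. At passages 1, 2, 3 and 4, before scaling by TMM, Zscan4c was 85.7, 31.9, 0.0960 and 0.0796 CPM, Zfp352 7.59, 13.9, 0.480 and 0, and Sox17 62.5, 55.8, 0.864 and 0.318. At passage 12 with doxycycline, outside this comparison, they were 60.7, 25.5 and 33.3 CPM.

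In edgeR 2030 of 15670 genes rose and 1882 fell. The count was 6602 without ZHBTc4 passage 1, whose length slope was -1.50, 2299 without ZHBTc4 passage 3, 1726 without mTBLC passage 1, 1077 without passage 2 and 1318 without passage 4. With passages 1, 2 and 4 matched as a replicate block 1508 genes passed. In single libraries Pou5f1 was 620 CPM before scaling by TMM in ZHBTc4 cells in S/L medium and 155 with doxycycline, 86.6 in 2MYCP medium at passage 12 and 1.07 with doxycycline, and 0 and 0.886 in 2MYC medium with doxycycline. Krt8 in the same libraries was 181 and 1186, 4633 and 2958, and 299.8 and 3425 CPM. The low Pou5f1 of the passage 12 library without doxycycline leaves its untreated state uncertain.

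**Figure D2:**
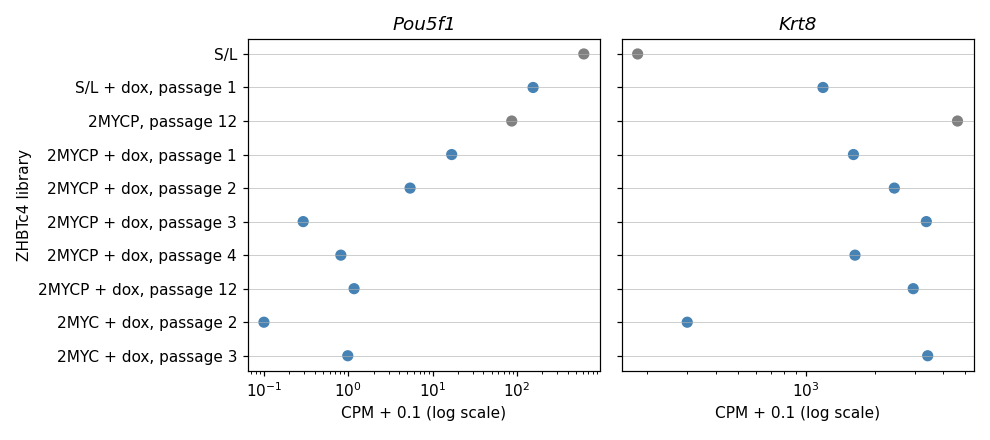
Pou5f1 and Krt8 in each library titled ZHBTc4, as CPM plus 0.1 on a log axis, with 1 point per library, grey without and blue with doxycycline. Pou5f1 was 620 CPM in S/L medium and 1.07 CPM or lower at passages 3, 4 and 12 in 2MYCP with doxycycline.

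When mTBLCs were moved to S/L medium (20 libraries over 92 h), endoderm genes rose and 2-cell genes fell. Levels are means over the first 12 h (n = 4) and the last 24 h (n = 6), and log2 changes are from 0 to 92 h on a fitted curve. Zscan4c fell from 122 ± 6.70 to 35.9 ± 13.4 CPM (log2 fold change -2.43 ± 0.34, adjusted p = 6.49e-06), with Zfp352 (-2.34), Usp17la (-3.25) and Pramel6 (-7.93). For the 33 2-cell genes tested, 0 rose, 31 fell and 2 did not pass (0 and 31 adjusted over the list alone, camera adjusted p = 1.34e-17, adjusted p = 0.142 with an estimated correlation). Col4a1 rose from 217 ± 52.9 to 2428 ± 591 CPM (log2 fold change 4.36 ± 0.15, adjusted p = 3.19e-15), and Cubn (8.72), Sox17 (4.16) and Gata6 (2.52) rose. The libraries after 60 h fell into alternating sets, seen after the values were examined. Before scaling by TMM, Gata6 was 143 to 150.2 CPM and Sox17 56.8 to 97.6 at 68, 76 and 92 h, and 61.1 to 79.7 and 18.7 to 21.9 at 72, 80 and 88 h. Without the 92 h library the log2 changes of Gata6 and Sox17 were 2.15 and 3.23. For the 20 primitive endoderm genes tested, 18 rose, 1 fell and 1 did not pass (18 and 1 adjusted over the list alone, camera adjusted p = 7.56e-42, adjusted p = 4.10e-05 with an estimated correlation). Spink1 (4.81) and Ttr (4.04) rose. For the 11 visceral endoderm genes tested, 8 rose, 1 fell and 2 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.00777, adjusted p = 0.142 with an estimated correlation).

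Pou5f1 was 1208 ± 85.0 early and 1184 ± 121 CPM late (adjusted p = 0.656), and Nanog 477 ± 54.7 and 394 ± 102 (adjusted p = 0.1). H19 (4.20), Cdkn1c (2.93) and Igf2 (2.44) rose and Plagl1 fell (-2.57). For the 21 imprinted genes tested, 12 rose, 2 fell and 7 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 4.53e-05, adjusted p = 0.0172 with an estimated correlation). The fibroblast genes Col6a3 (-4.36) and Dcn (-3.37) fell. For the 13 fibroblast genes tested, 0 rose, 10 fell and 3 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 1.75e-06, adjusted p = 0.0056 with an estimated correlation). Cdx1 (-5.28), Wnt3a (-3.22) and Notum (-2.23) fell and Lef1 rose (4.07). For the 18 Wnt targets tested, 3 rose, 7 fell and 8 did not pass (3 and 7 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.0497 with an estimated correlation). Gata3 (-1.98) and the germline gene Dazl (-2.17) fell, and Bub1 (1.73) and Top2a (1.15) rose. In edgeR 3580 of 16846 genes rose and 3245 fell, 11763 changed at some point of the course, and a curve with 2 degrees of freedom in place of 3 gave 9984.

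In SFH medium (23 libraries over 96 h) naive pluripotency genes fell and formative and endoderm genes rose. Over the first 12 h (n = 4) and from 68 h on (n = 8), Fgf5, a marker of the primed epiblast, rose from 0.305 ± 0.373 to 63.0 ± 24.8 CPM (log2 fold change 9.02 ± 0.59, adjusted p = 2.24e-13), with Pou3f1 (3.74), Wnt8a (5.86) and Dnmt3b (3.20). For the 15 formative genes tested, 12 rose, 2 fell and 1 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 5.80e-13, adjusted p = 0.00217 with an estimated correlation). Zfp42 fell from 654 ± 80.4 to 79.0 ± 23.2 CPM (log2 fold change -3.44 ± 0.21, adjusted p = 3.49e-14), Sox2 (-2.10), Nanog (-1.68), Esrrb (-4.79) and Tfcp2l1 (-4.61) fell, and Pou5f1 fell less (1278 ± 110.4 to 791 ± 71.8 CPM, log2 fold change -0.68 ± 0.10, adjusted p = 2.64e-06). Of 20 tested naive pluripotency genes, 2 rose, 17 fell and 1 did not pass (2 and 17 adjusted over the list alone, camera adjusted p = 1.98e-18, adjusted p = 0.00217 with an estimated correlation). Zscan4c fell (-3.17), with Zfp352 (-3.17) and Pramel6 (-12.13). Of 32 tested 2-cell genes, 0 rose, 29 fell and 3 did not pass (0 and 30 adjusted over the list alone, camera adjusted p = 6.66e-31, adjusted p = 0.00217 with an estimated correlation).

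Cubn (20.0 ± 24.1 to 2694 ± 490.4 CPM, log2 fold change 8.64 ± 0.35, adjusted p = 2.88e-18), Dab2 (6.12), Gata6 (3.19) and Sox17 (4.64) rose. Of 20 tested primitive endoderm genes, 18 rose, 1 fell and 1 did not pass (18 and 1 adjusted over the list alone, camera adjusted p = 2.98e-38, adjusted p = 0.00113 with an estimated correlation). Spink1 (9.03), Ttr (8.68) and Apoa4 (10.44), genes of the yolk sac endoderm, rose. Of 14 tested visceral endoderm genes, 10 rose, 1 fell and 3 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 2.11e-06, adjusted p = 0.00564 with an estimated correlation). H19 (6.40) and Cdkn1c (4.31) rose. Of 21 tested imprinted genes, 12 rose, 1 fell and 8 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 1.57e-07, adjusted p = 0.0075 with an estimated correlation). Krt8 rose (1.42). The fibroblast genes Col6a3 (-6.29) and S100a4 (-4.23), the germline gene Dazl (-5.19) and the p53 target Cdkn1a (-1.86) fell. In edgeR 3510 of 16343 genes rose and 3218 fell, and 10553 changed at some point.

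The course in SFH was tested against that in S/L by the difference of their 0 to 92 h changes (23 against 20 libraries), where a positive value, counted below as a rise, is a change to a higher level in SFH than in S/L. Fgf5 (log2 fold change 8.16 ± 0.99, adjusted p = 6.23e-08), Wnt8a (8.56), Pou3f1 (3.57) and Sall2 (3.37) had positive differences. Of 15 tested formative genes, 10 rose, 1 fell and 4 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 1.25e-10, adjusted p = 3.74e-04 with an estimated correlation). Tcl1 (-5.75), Esrrb (-3.89), Zfp42 (-2.86), Sox2 (-2.07), Nanog (-1.12) and Pou5f1 (-0.72) had negative differences. The alternating S/L sets after 60 h parted Zfp42 and Nanog too. Before scaling by TMM, they were 583 to 709 and 406 to 483 CPM at 68, 76 and 92 h. At 72, 80 and 88 h they were 210 to 391 and 219 to 405 CPM, so the 92 h end lies in the higher set. For the 20 naive pluripotency genes tested, 1 rose, 16 fell and 3 did not pass (1 and 17 adjusted over the list alone, camera adjusted p = 6.04e-27, adjusted p = 5.62e-06 with an estimated correlation). Apob (5.11), Ttr (4.38) and Spink1 (4.06) had positive differences. For the 14 visceral endoderm genes tested, 7 rose, 0 fell and 7 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 9.93e-06, adjusted p = 0.00503 with an estimated correlation). For Zscan4c the difference was -0.70 (adjusted p = 0.289), and for Pramel7 it was -7.13 (adjusted p = 2.68e-04). For the 33 2-cell genes tested, 0 rose, 4 fell and 29 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.0335, adjusted p = 0.623 with an estimated correlation). In edgeR 941 of 17745 genes had a positive and 1171 a negative difference, and a curve with 2 degrees of freedom gave 4998. The courses came from separate tables, so medium and table cannot be told apart.

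**Figure D3:**
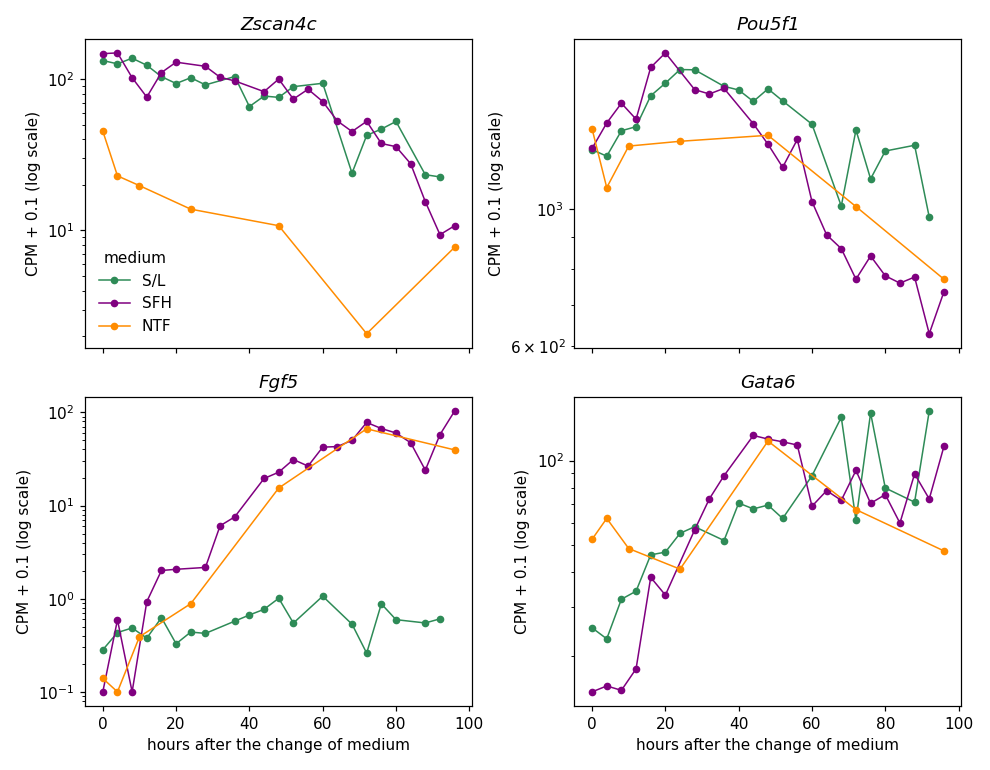
Zscan4c, Pou5f1, Fgf5 and Gata6 as CPM plus 0.1 on log axes against hours after the change of medium, with 1 point per library of the S/L (n = 20), SFH (n = 23) and NTF courses (n = 7). Fgf5 climbed in SFH and NTF and stayed near its starting level in S/L.

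In NTF medium (7 libraries over 96 h) Fgf5 rose from 0.104 ± 0.148 CPM in the first 12 h (n = 3) to 58.0 ± 20.6 at 72 and 96 h (n = 2, log2 fold change 10.99 ± 0.68, adjusted p = 2.58e-06), with Fgf15 (6.35) and Zic5 (5.97). For the 15 formative genes tested, 13 rose, 1 fell and 1 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 6.12e-14, adjusted p = 0.077 with an estimated correlation). Esrrb (-4.74), Zfp42 (-4.01), Tcl1 (-5.29), Sox2 (-2.31) and Nanog (-1.41) fell. Of 20 tested naive pluripotency genes, 2 rose, 14 fell and 4 did not pass (2 and 14 adjusted over the list alone, camera adjusted p = 1.40e-09, adjusted p = 0.148 with an estimated correlation). Zscan4c (27.5 ± 14.3 to 5.28 ± 4.42 CPM, log2 fold change -2.33 ± 0.66, adjusted p = 0.0191) and Zfp352 (-4.66) fell. Of 32 tested 2-cell genes, 0 rose, 25 fell and 7 did not pass (0 and 26 adjusted over the list alone, camera adjusted p = 6.60e-14, adjusted p = 0.236 with an estimated correlation). Cubn (6.64) and Dab2 (4.96) rose, as did Ttr (10.28) and Apob (10.13). For the 20 primitive endoderm genes tested, 12 rose, 3 fell and 5 did not pass (12 and 3 adjusted over the list alone, camera adjusted p = 1.59e-08, adjusted p = 0.0604 with an estimated correlation). Of 13 tested visceral endoderm genes, 10 rose, 0 fell and 3 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 8.67e-11, adjusted p = 0.077 with an estimated correlation).

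Top2a (2.01) rose. For the 17 proliferation genes tested, 16 rose, 0 fell and 1 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 2.14e-07, adjusted p = 0.236 with an estimated correlation). H19 (4.66) and Peg3 (5.33) rose, and Col1a1 (-5.62), Gata3 (-2.48, a call lost without 4 h or 72 h) and Dazl (-5.13) fell. The heart muscle genes Myl4 (-7.49) and Tnnt2 (-7.26) fell. For the 12 cardiac genes tested, 0 rose, 5 fell and 7 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 0.00576, adjusted p = 0.236 with an estimated correlation). In edgeR 2729 of 16381 genes rose and 2508 fell.

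TELC and PreLC cells, both in SFH medium at passages 0 to 2, were compared as 3 against 3. Gata6, a primitive endoderm factor, was 92.5 ± 56.0 against 429.6 ± 118 CPM (adjusted p = 0.254), Nanog 52.4 ± 33.3 against 8.45 ± 3.02 CPM (adjusted p = 0.243), Krt8 845 ± 645 against 220.1 ± 188 CPM (adjusted p = 0.307) and Fgf5 76.4 ± 29.0 against 13.8 ± 0.768 CPM (adjusted p = 0.243), none past the test. Lower by camera in TELC were primitive endoderm genes (0 rose, 0 fell and 20 did not pass of 20, 0 and 4 adjusted over the list alone, camera adjusted p = 5.28e-06, adjusted p = 0.45 with an estimated correlation) and proliferation genes (0 rose, 0 fell and 17 did not pass of 17, 0 and 0 adjusted over the list alone, camera adjusted p = 6.80e-04, adjusted p = 0.469 with an estimated correlation). Higher were fibroblast genes (0 rose, 0 fell and 13 did not pass of 13, 0 and 0 adjusted over the list alone, camera adjusted p = 6.35e-06, adjusted p = 0.45 with an estimated correlation) and cardiac genes (0 rose, 0 fell and 13 did not pass of 13, 3 and 0 adjusted over the list alone, camera adjusted p = 0.00346, adjusted p = 0.45 with an estimated correlation). In edgeR 0 of 16564 genes passed and 2582 had an unadjusted p under 0.05, while DESeq2 called 783 higher and 119 lower. Without TELC passage 0, 1938 genes rose and 2590 fell, and without PreLC passage 2, 128 passed. TELC passages 1 and 2 had length slopes of -2.21 and -1.96 and 19.3% and 13.5% ribosomal protein counts, against -0.25 and 5.45% at passage 0.

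Against the EB-TSC library (n = 1, TSC medium), TELC (n = 3) had the semaphorin gene Sema3e lower (8.66 ± 1.59 against 156 CPM, log2 fold change -4.17), the single gene called in edgeR, and Krt8 was 845 ± 645 against 1931 CPM (adjusted p = 0.533). Higher by camera in TELC were visceral endoderm genes (0 rose, 0 fell and 15 did not pass of 15, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.941 with an estimated correlation), and lower were imprinted genes (0 rose, 0 fell and 20 did not pass of 20, 1 and 3 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.941 with an estimated correlation). In edgeR 1 gene passed, 2870 of 16564 had an unadjusted p under 0.05, and DESeq2 called 912 higher and 281 lower. The edgeR count was 0 with the length trend removed, 0 without TELC passage 1 or 2, 2 with no filter, and 3702 without TELC passage 0.

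Blastoids (TNKM medium, n = 2) were compared with an E3.5 blastocyst sample from ICR embryos (n = 1), with the spread taken from the other groups of the fit. The differences cannot be told from those of this single library or of its strain. In blastoids the trophectoderm genes that fell included Cdx2 at 21.7 ± 16.1 against 526 CPM (log2 fold change -4.60 ± 1.03, adjusted p = 0.0273), Gata3 at 4.66 ± 0.606 against 399 CPM (log2 fold change -6.42 ± 1.56, adjusted p = 0.037) and Tspan8 (-5.71), while Krt8 was 562 ± 58.7 against 1388 CPM (adjusted p = 0.504). For the 25 trophectoderm genes tested, 0 rose, 9 fell and 16 did not pass (2 and 11 adjusted over the list alone, camera adjusted p = 9.60e-09, adjusted p = 0.0362 with an estimated correlation). Endoderm genes that rose included Col4a2 at 4986 ± 221 against 72.1 CPM (log2 fold change 6.11 ± 0.98), Sox17 (3.36) and Foxq1 (6.51). Gata6, of the same list, ran the other way at 63.5 against 268 CPM (log2 fold change -2.08), though it did not pass the test. Of 20 tested primitive endoderm genes, 11 rose, 0 fell and 9 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1.37e-08, adjusted p = 0.323 with an estimated correlation). The imprinted genes H19 (4020.0 ± 223 against 6.68 CPM, log2 fold change 9.23 ± 0.93, adjusted p = 0.00268), Meg3 (8.71) and Peg10 (8.34) rose. For the 20 imprinted genes tested, 11 rose, 0 fell and 9 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 8.80e-10, adjusted p = 0.0856 with an estimated correlation). Pramel7 had 0 counts in both blastoid libraries against 278 CPM (at least 4603-fold lower).

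The p53 targets Btg2 (4.79) and Plk2 (6.16) rose. Of 20 tested p53 targets, 9 rose, 1 fell and 10 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 5.90e-05, adjusted p = 0.303 with an estimated correlation). Etv4 (7.34), a target of FGF signalling, Rnf43 (6.67) and Ddit4 (3.58) rose and Wnt3a (-6.74) fell. Fgf5 was 3.77 ± 2.40 CPM and had 0 counts in the blastocyst library (at least 18-fold higher). Tfcp2l1, a naive factor, fell (-3.82), and Pou5f1 was 227 ± 41.4 against 882 CPM (adjusted p = 0.101). In edgeR 904 of 16564 genes were higher and 376 lower, with 2989 in DESeq2. The median log2 difference of all genes was 0.26 with TMM and 0.14 with the size factors of DESeq2. The count was 286 (234 up) without blastoid 1, 325 (273 up) without blastoid 2, and 2907 in a fit without TELC passages 1 and 2.

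Embryoid bodies from mTBLCs and from TC1 cells were compared at days 3, 8, 10 and 12 in serum medium (4 against 4, day as a block). Pou5f1 was 284 ± 486 against 531 ± 706 CPM (adjusted p = 0.992) and Gata6 85.0 ± 26.4 against 49.6 ± 28.1 CPM (adjusted p = 0.992). Higher by camera in mTBLC bodies were primitive endoderm genes (0 rose, 0 fell and 20 did not pass of 20, 0 and 0 adjusted over the list alone, camera adjusted p = 1.76e-10, adjusted p = 0.49 with an estimated correlation), visceral endoderm genes (0 rose, 0 fell and 14 did not pass of 14, 0 and 0 adjusted over the list alone, camera adjusted p = 7.28e-06, adjusted p = 0.546 with an estimated correlation) and blood genes (0 rose, 0 fell and 13 did not pass of 13, 0 and 0 adjusted over the list alone, camera adjusted p = 2.14e-04, adjusted p = 0.49 with an estimated correlation). Lower were proliferation genes (0 rose, 0 fell and 17 did not pass of 17, 0 and 0 adjusted over the list alone, camera adjusted p = 1.34e-06, adjusted p = 0.67 with an estimated correlation) and neural genes (0 rose, 0 fell and 15 did not pass of 15, 0 and 0 adjusted over the list alone, camera adjusted p = 1.39e-04, adjusted p = 0.49 with an estimated correlation). In edgeR 0 of 15546 genes passed and 367 had an unadjusted p under 0.05, with 8 in DESeq2. Without the day block 0 genes passed (229 at an unadjusted p under 0.05). Before scaling by TMM the mTBLC library labelled day 3 had 18.9 CPM of Pou5f1 and 2854 of Col1a1, and the one labelled day 8 had 944 CPM of Pou5f1. With days 10 and 12 alone, chosen after the data were seen, 711 genes rose and 793 fell.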

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

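The tests of gene length, of library type, of the order of embryoid body days and of a repeated library were chosen after the result was seen, and the others were written down before.

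In other splits of the same libraries, mTBLCs against mPSCs gave the most genes in 1 of 35 splits, the real one (3402 genes, highest other 2). The same held for 2MYCP against 2MYC without the passage block (1 of 35, 2055 genes, highest other 0), blastomere-derived lines with their doses merged against mPSCs (1 of 35, 4950, highest other 0) and against mTBLCs (1 of 35, 5192, highest other 0), and the SFH against the S/L course (1 of 40 drawn splits, 2112, highest other 53). A split that mixes differing groups widens the spread within its arms, so it gives few genes whatever sets the groups apart. A difference of deposited set, strain or culture would do the same, so these splits bear on none of those. For ZHBTc4 with doxycycline 1 of 35 splits reached the 3912 genes of the real one, and the highest other gave 3166, parting ZHBTc4 passage 1 and the mTBLCs from ZHBTc4 passages 2 to 4. TELC and PreLC allow 10 splits, too few for a share under 0.05, and 10 of 10 gave as many genes as the real one (0 genes, highest other 0). For embryoid bodies the real split gave 0 genes, so 35 of 35 splits reach it by construction and the share says nothing. Those splits ignore the day pairing, and the highest other, with 97 genes, parted days 3 and 8 from days 10 and 12. Of the 8 splits that part every day's pair, with day as a block, the real one gave 0 genes and the highest other 0.

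The NTF library at 24 h stood apart in genes detected, with 15752 against 17394 to 18297 in the other NTF libraries. It had 5.10 M counts, the fewest of the course. This was the one flag among 24 tests (4 measures in groups of 4 to 10 libraries) against a 95% critical value, which chance passes in about 1 in 20, so a single flag is close to what chance gives. The change from 0 to 92 h differed between the SFH and S/L courses in 2112 genes by a test of the difference itself. Among libraries outside the report's tests, ZHBTc4 cells in 2MYC medium with doxycycline had Krt8 at 299.8 CPM, Gata3 at 787.9 and Cdx2 at 73.03 at passage 2, and 3425, 99.42 and 14.18 at passage 3, before scaling by TMM. The ZHBTc4 library in S/L medium had 181.4, 4.815 and 4.815, so the lower value of each gene, 299.8, 99.42 and 14.18, was above it, though Krt8 ran opposite to Gata3 and Cdx2 between the passages.

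The Ctnnb1 knock-out and ICG001 libraries shared a steep negative trend of expression with gene length, which might be a matter of library making. For Ctnnb1 itself, the log2 fold change was -1.99 ± 0.56 with the length trend removed, against -2.20 ± 0.67, so length bias is not the whole cause. A library type shared with others is left open, since 9 other libraries with a slope as low had Ctnnb1 from 198.7 to 819.1 CPM before scaling by TMM, the lowest 1.14 times the 173.6 CPM of the knock-out on that scale. That lowest value was of TELC passage 1, which had a steeper slope of -2.21. Slopes of -1.44 to -1.54, nearer the -1.49 of the knock-out, were those of gelatin P7, ICG001 and ZHBTc4 passages 1 and 12 in 2MYCP with doxycycline. These had 396.6 to 819.1 CPM, all above the knock-out, but they differ from it in treatment or line. Of the 2407 genes called with ICG001, 71.1% (1712) kept their call with the trend removed, so length bias is at most a part of that result. An effect of the knock-out or of ICG001 could not be told from the making of a single library.

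The mTBLC embryoid body libraries labelled day 3 and day 8 looked out of order. An exchange of these labels may explain it, as the library labelled day 8 correlated better with TC1 day 3 than the one labelled day 3, by 0.091 (0.859 against 0.768). Other values do not call for it: among TC1 bodies the library labelled day 8 was closest to day 8 (0.89), and the one labelled day 3 to day 12 (0.872, with 0.823 at day 8). As labelled, Pou5f1 ran 18.9, 944, 60.4 and 44.6 CPM before scaling by TMM. Exchanged, it would run 944, 18.9, 60.4 and 44.6 CPM, a fall after day 3 that goes with an exchange. Col1a1 would then run 4.33, 2854, 773 and 2438 CPM, no steady course, so an exchange is left open. TC1 day 3 correlated at 0.969 and 0.951 with 2 mPSC libraries and at 0.758 to 0.859 with the mTBLC embryoid bodies, unlike what an exchange of arms at day 3 would give. Its closest match, the first of these mPSC libraries, differed from it by a mean chi-square per gene of 3.9, the closest of 5356 pairs, so that a single library held in 2 places, and with it the arm at day 3, is left open.

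The genes lower on gelatin may be RNA of feeder cells in the other 2MYCP cultures, or a response of mTBLCs to the surface. Over the S/L course, where fibroblast genes fell, the median rho with the fibroblast list was 0.21 over the 544 genes expressed there, of the 664 called more than 8-fold lower. This was above the upper bound of 0.13 of random lists but under the 0.5 set beforehand, which leaves this open. Gene length was excluded as the cause of the whole, since 86.4% of the genes called lower (1304 of 1509) stayed so with the length trend removed.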

How the results depend on the processing

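The alternatives with halved counts, the length trend removed, fits without the passage 0 library or without TELC passages 1 and 2, embryoid bodies without days 3 and 8, ZHBTc4 passages 2 and 4 alone and the NTF course without 4 h and 24 h were chosen after the result was seen.

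Of 243 alternatives for the counts of genes and lists, 159 stayed within 1.5 times and 84 moved. Of 4197 alternatives for 329 gene results, 3686 (87.8%) kept their direction and side of the test, 484 lost the call, 17 gained one and 10 reversed. The share kept was 98.4% in the S/L course, 97.2% in the NTF course, 96.8% for the blastomere-derived lines against mPSCs, 95.4% for mTBLCs against mPSCs, 57.6% for the passage trend and 59.2% for 2MYP. The cause was not tested except where fewer libraries or genes show it.

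The Wald test of DESeq2 gave 3642 genes for the passage trend, 3090 for 2MYC, 4429 for gelatin, 3006 for 2MYP, 1566 for the knock-out, 4188 for ICG001, 902 for TELC against PreLC, 1193 against EB-TSC, 2989 for blastoids and 8 for embryoid bodies, more than edgeR in each. For the knock-out, no filter gave 63 genes, the stricter one 0, halved counts 8 and the length trend removed 100. TELC against EB-TSC gave 2 with no filter and 0 with the length trend removed or without TELC passages 1 and 2.

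With P6 and P8 as controls, with fewer libraries, gelatin gave 418 genes (35 up and 383 down), ICG001 72, and 2MYP and the knock-out 0 each. Without the passage 0 library in the fit, gelatin gave 6518, 2MYP 5029, the knock-out 4277, ICG001 6252 and the blastomere-derived lines against mTBLCs 7859. Blastoids gave 2907 without TELC passages 1 and 2, and embryoid bodies 1504 without days 3 and 8. The 0 h course libraries in place of mTBLCs gave 1353, passage as a plain number 0, and a spline with 2 degrees of freedom 4998 for the courses' difference.

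With passages matched as a replicate block, ZHBTc4 gave 1508 genes, TELC against PreLC 0 and the doses of blastomere-derived lines 0. Without the replicate block, 2MYCP against 2MYC gave 2055 and embryoid bodies 0. Leaving out a passage of 2MYCP and 2MYC gave 407 without passage 1, 215 without passage 2 and 792 without passage 4.

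Leaving out 1 of the compared libraries, so not the passage 0 library where it only shares the fit, gave 1592 to 4103 genes for mTBLCs against mPSCs, 0 to 3046 for the trend, 466 (84 up and 382 down) to 1705 (532 and 1173) for gelatin, 1 to 446 for 2MYP, 0 to 1 for the knock-out, 683 to 1067 for ICG001, 2781 to 6057 and 2540 to 4156 for the blastomere-derived lines against mPSCs and mTBLCs, 1077 to 6602 for ZHBTc4, 0 to 4528 for TELC against PreLC, 0 to 3702 against EB-TSC, and 286 to 325 for blastoids.

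Lists called by camera fell from 139 to 15 with the correlation estimated. The 10 reversed values were of genes short of the test before and after: Zscan4c on gelatin (-0.17 to 0.87 leaving out 1 library), Ctnnb1 in 2MYP (-0.19 to 0.13, 0.10 with the length trend removed, 0.013 with P6 and P8 as controls), Cdx2 in ZHBTc4 (-1.16 to 1.87, and -0.89 with passages 2 and 4 alone), Pou5f1 in the S/L course (-0.20 with 2 degrees of freedom, -0.049 without 0 h), Krt8 in TELC against PreLC (-0.30 without TELC passages 1 and 2) and Pou5f1 in embryoid bodies (0.32 without day 3).

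Depth limits most the libraries with the fewest counts, 1.04 and 5.85 M in ZHBTc4, 5.10 and 5.77 M in the NTF course, 6.26 to 7.98 M in 2MYC and 7.28 M in an mPSC library.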

Other observations

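No hypothesis beyond the tests above was added and none was tested here. The libraries below were picked after their values were seen.

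Krt8 and Gata3, early markers of trophectoderm, were measured in ZHBTc4 libraries that belonged to no comparison, given here in CPM before scaling by TMM. In S/L medium Krt8 was 181.4 CPM without doxycycline and 1186 CPM with it, and Gata3 4.815 and 19.44 CPM. In 2MYCP medium at passage 12 Krt8 was 4633 CPM without doxycycline and 2958 CPM with it, and Gata3 27.03 and 76.34 CPM. Pou5f1 was 86.57 CPM in the passage 12 library without doxycycline, against 619.8 CPM in S/L medium and 821.3 to 1124 CPM in TC1-GFP mTBLCs. With Pou5f1 that low, it is uncertain whether this library was free of doxycycline, as its title implies.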
